A study of Mus musculus with 4 samples.

How the data were processed

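Total kidney RNA from 2 control and 2 MN samples was labelled with Cy3 and hybridized to Agilent whole-genome mouse arrays, 1 sample per array, per the labels' protocols (0.2 µg of RNA labelled, 0.6 µg of labelled RNA fragmented for hybridization). The deposited scanner files hold spot intensity on a linear scale. Per the file headers, Agilent Feature Extraction 10.5.1.1 subtracted background, removed spatial and multiplicative trends, and put surrogate values in place of spots that did not rise above background (16.0% and 6.91% of non-control spots on control arrays 1 and 2, and 17.7% and 20.0% on MN arrays 1 and 2); it did not scale arrays to each other. The deposited value table of the series holds log2 values whose making is not given in the sources used here. Set against the scanner values over 55821 probes, it matched log2 signal scaled to each array's 75th percentile, minus the mean of the 2 control arrays, with column medians of 0.03 and -0.03 for control and -0.03 and -0.04 for MN. Its columns for replicates 1 and 2 were exchanged in both groups relative to the scanner files (correlation over probes of 0.999 with the other replicate's array). Which of the orders is right is unknown. Group means do not depend on it, and it was used only as an alternative.

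Each array had 62976 spots, of which 59305 were non-control spots of 55681 probes. Control spots and spots marked as non-uniform were left out and the spots of a probe were averaged. Values were log2 of the processed signal minus each array's 75th percentile of non-control spots. A probe entered the tests if it was well above background on both arrays of at least 1 group, and a gene with several probes was represented by the one with the highest mean over the 4 arrays, chosen without regard to group. This left 25290 genes, of which 7372 had more than 1 probe; among 371 such genes at an unadjusted p under 0.05, probes of 86 gave estimates of both signs. Gene names followed the accession in a RefSeq gene table of another mouse assembly, GRCm38.p6 (28051 probes), the symbol (3406) or a single synonym (290), and otherwise the file (23749). A further 185 probes of antibody gene segments, listed in the files by transcript, were named from the files' description column; that step was added after the files were seen. The 2 slides carried different versions of the annotation (1831 probes with different gene names), and the version of slide 2 was used. The probes' own positions are on mm9, per the file headers: that of Slpi lies on chromosome 2 at 164179849 to 164179908 and that of Cfd on chromosome 10 at 79355302 to 79355361.

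Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over genes, threshold 0.05; residual df 2, prior df 1.99). Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and beside it with an estimated correlation and with fry; a list needed at least 3 measured members. A gene not well above background on either array of a group, by any of its probes, was given a lower bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

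The slides were read from the file headers. Slide, scan and replicate number coincide, so a block for the slide is also a block for the replicate number; deviations of same-numbered arrays from their group means correlated at 0.63 across genes. The fit without a block was fixed as the main one before the data were examined, as were the gene lists, the alternatives and the rule for named genes. That rule took the 12 largest rises and falls among genes past the threshold that were well above background on all 4 arrays with both MN arrays beyond both control arrays, filled up by the smallest unadjusted p among genes differing by 2-fold or more; up to 5 genes per direction with the largest lower bound; up to 4 members of each list with the largest absolute difference; and genes fixed for their part in the disease, among them Pla2r1, Thsd7a, Nphs1, Lcn2, Havcr1, C3 and the Ighg genes. Not every gene the rule takes is named in the text. Predicted genes and clones were left out. Derl3, Sdc1, Prdm1, Irf4, Tcf21 and Ciart were named from their lists after their values were seen.

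The alternatives were normexp background correction with an offset of 50, quantile or median scaling, the deposited value table, no filter or a stricter one, other probe rules, other variance models, a threshold of 0.1, the block, each array left out in turn and other set tests. The scripts were tested on simulated data with 25290 genes, the real means and slide effect, and 200 changed genes in each of 20 simulations. Without a block, 0% of genes changed by 1 on the log2 scale were recovered, 0.0746% of those changed by 2 and 61.6% of those changed by 4, with 0.3 false calls per simulation. With the slide as a block the shares were 0.149%, 41.8% and 89.8%, with 5.85 false calls. A list of 25 genes shifted by 0.3 was found by camera at the preset correlation in 20 of 20 simulations, and in 0 with an estimated correlation or with fry. Simulated genes were independent of each other.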

Results

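Whole-kidney gene expression was measured with 1-colour Agilent arrays in female BALB/C mice with experimental membranous nephropathy (MN), a glomerular disease in which antibody and antigen are deposited along the outer side of the glomerular filter. The mice were 6 weeks old at the start per the labels. Both groups were first immunized with cationic bovine serum albumin (0.2 mg, in complete Freund's adjuvant). From 2 weeks afterwards the MN group received the same antigen intravenously at 13 mg/kg, 3 times per week for 6 weeks, while the control group received vehicle, called saline in one part of the labels and PBS in another. The groups therefore differ in the repeated intravenous antigen and not in the first immunization. The series held 2 control and 2 MN samples, 1 array each. The labels do not say that each array came from a separate animal, so the p-values measure the spread between these samples. Each slide held 1 control and 1 MN array (replicate 1 of both groups on slide 1 and replicate 2 on slide 2). Spots well above background made up 65.9% and 79.5% of non-control spots on the control arrays and 64.0% and 63.1% on the MN arrays, no spot was saturated, and the median raw signal was 3.18 to 5.37 times the local background. The slope of the spiked-in control transcripts was outside the software's range on both arrays of slide 1 (0.895 for control and MN). It was inside the range on slide 2 (0.949 for control and 0.968 for MN). The number of arrays limits the precision of every value below.

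The first comparison asked which genes differed between MN and control kidneys. The rises past the threshold were in an antibody gene segment and in transcripts of other secreted proteins. Among 25290 genes tested with limma, 5 were higher in MN and 0 were lower (adjusted p under the threshold), and all 5 changed by more than 2-fold. Igkv3-10, a variable segment of the antibody kappa light chain, rose by 5.13 ± 0.14 (log2, SE; 35.0-fold), with 6.44 from a second probe. Slpi, a secreted inhibitor of neutrophil proteases, rose 21.3-fold (log2 difference 4.41 ± 0.15). Cfd, the complement protease factor D that is also known as adipsin, went from a log2 level of -5.13 ± 0.22 (SD, n = 2) in control to 1.79 ± 0.28 in MN, and was well above background on 1 of the 2 control arrays. Adipoq, the adipocyte hormone adiponectin, and Mup18, a major urinary protein, were not well above background on either control array; they were at least 20.6-fold and at least 25-fold higher in MN, a bound set by the lowest signal well above background on the control arrays. All 5 genes had an adjusted p of 0.046 and were higher in MN on both slides.

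At an unadjusted p under 0.05, 893 genes were higher and 883 lower, of which 217 and 199 differed by 2-fold or more. With the slide as a block, limma called 0 genes at the same threshold, the smallest adjusted p was 0.0579, and 1588 genes were higher and 2289 lower at an unadjusted p under 0.05. Within slides 1 and 2 the log2 differences were 5.19 and 5.07 for Igkv3-10, and 4.37 and 4.46 for Slpi, and on slide 2 it was 6.97 for Cfd; those of Cfd on slide 1 and of Adipoq and Mup18 rest on control signals near background and are not given. With normexp background correction Igkv3-10 was at 3.66, Slpi at 4.05 and Cfd at 5.08, all past the threshold, while Adipoq was at 2.48 and Mup18 at 2.58, both with an adjusted p of 0.0517, and Mup18 had an adjusted p of 0.0856 with quantile normalization. Over the alternatives that tested these genes the adjusted p ran from 0.0225 to 0.477 for Adipoq and from 0.0303 to 0.477 for Mup18. Igkv and Mup probes can bind transcripts of near-identical relatives, so which family member gave the signal is uncertain.

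**Figure D1:**
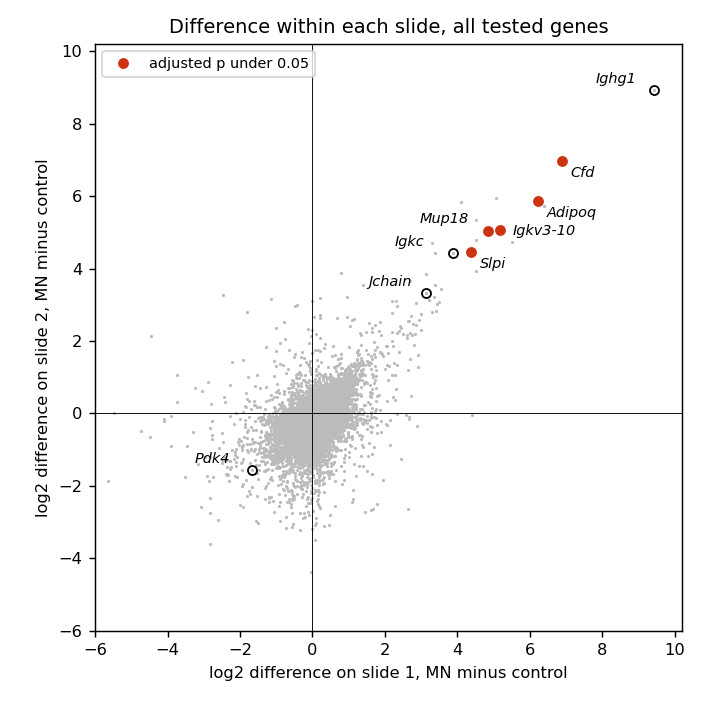
Log2 difference between the MN and the control array of slide 1 (horizontal) and of slide 2 (vertical) for each of 25290 tested genes. Red points are the 5 genes past the threshold and open circles are 4 other genes that did not pass it. The control signals of Ighg1, Adipoq and Mup18, and that of Cfd on slide 1, were not well above background.

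Other genes with large differences did not pass the threshold. Ighg1, the constant region of the IgG1 heavy chain, had a log2 level of 2.76 ± 0.25 (SD, n = 2) in MN, and its brightest probe was not well above background on either control array (adjusted p = 0.052, and 0.0102 to 0.477 over the alternatives). The log2 difference of that probe was 9.17, or 6.12 with normexp, and a second probe gave 5.15, so its size is uncertain. Igkc, the kappa constant region, differed by 4.14 ± 0.22 and Jchain, which links antibody units into polymers, by 3.23 ± 0.15 (adjusted p = 0.071 and 0.066). Further genes with higher values in MN were Igkv3-7 (3.19), Igkv3-4 (4.94), the carbonic anhydrase Car3 (3.46), the lipid droplet gene Cidec (2.59, with 0.27 from a second probe), Mup19 (2.95), Rspo1, a secreted activator of WNT signalling (2.61), the matrix gene Thbs4 (2.41) and the transcription factor gene Zbtb16 (2.33), with adjusted p from 0.052 to 0.105. Normexp background correction, whose offset pulls dim genes towards 0, gave 3.05 for Igkv3-4, 2.29 for Car3, 1.71 for Cidec, 1.64 for Rspo1 and 1.19 for Thbs4.

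Among genes with lower values in MN none passed. Pdk4, a kinase that restrains glucose oxidation, had a log2 difference of -1.62 ± 0.14 (adjusted p = 0.160). The methyl-transfer enzyme Bhmt was at -1.29, the transcriptional regulator Cited1 at -1.22, Cyp27b1, which makes active vitamin D, at -1.17, and the interleukin receptor chain Il15ra at -1.10. Xlr3b (-1.27), Elavl3 (-1.07, and -0.64 with normexp), Slc25a25 (-1.05) and Ifitm7 (-1.10) lay in the same range. Adjusted p for the 12 genes named by this rule ran up to 0.316. For Il15ra, Ifitm7, Bhmt, Dmtn, Dpysl5 and Igsf9 another probe gave a value closer to 0 or above it, such as 0.32 for Dpysl5 against the -1.09 of its brightest probe.

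**Figure D2:**
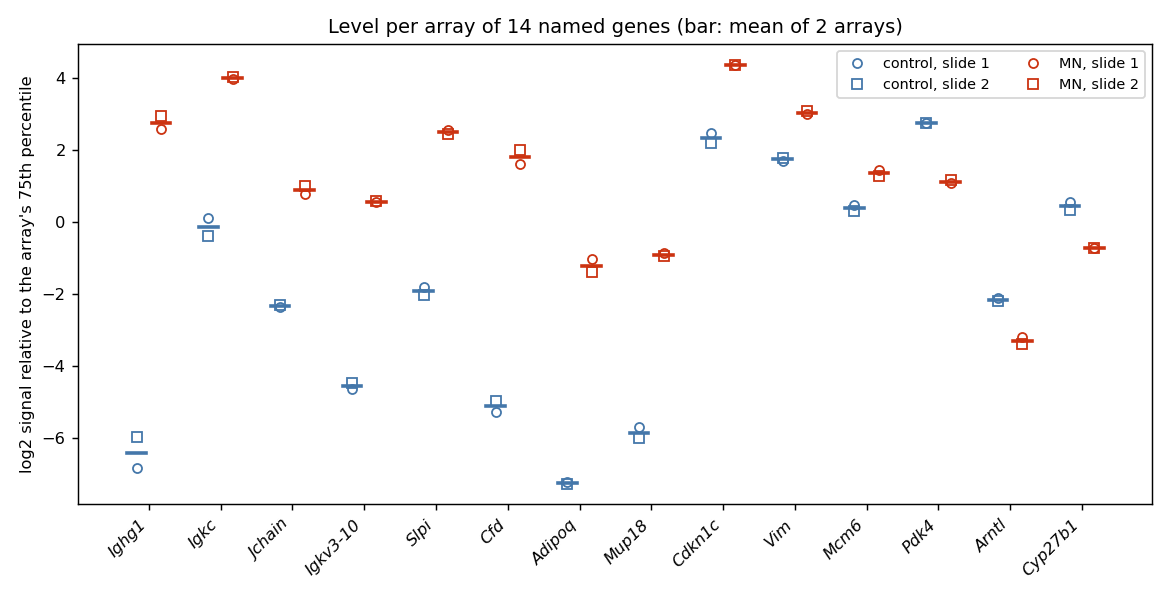
Log2 signal of 14 named genes relative to the 75th percentile of each array, with circles for slide 1, squares for slide 2 and a bar for the mean of the 2 arrays of a group (control blue, MN red). In each of these genes both MN arrays lie beyond both control arrays. The control points of Ighg1, Adipoq and Mup18, and that of Cfd on slide 1, were not well above background.

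The genes fixed beforehand for their part in membranous nephropathy showed small differences apart from the antibody genes. Transcripts of the 2 podocyte antigens of the human disease differed by 0.16 ± 0.15 (Pla2r1) and -0.35 ± 0.24 (Thsd7a). The slit diaphragm gene Nphs1 differed by -0.02 ± 0.27 (0.09 with quantile normalization). The tubular injury genes Lcn2 and Havcr1 were at 0.40 and 0.20, and the complement gene C3 at -0.30 ± 0.18. None of these passed (adjusted p of 0.787 or more). Of the other IgG subclasses, Ighg2b differed by 1.23 ± 0.15 (0.44 with normexp) and Ighg2c by -0.14 ± 0.18 (0.04 with quantile normalization). The Ighg2c probe was dim, with log2 levels of -4.69 in control and -4.83 in MN. It was well above background on only 1 of the 2 MN arrays, so its value does not show that this subclass was unchanged.

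The second comparison asked whether 32 lists of genes fixed beforehand moved together. With limma's camera at a preset inter-gene correlation of 0.01, 17 lists were higher in MN, 4 were lower and 11 did not pass. With an estimated correlation 0 lists passed (smallest adjusted p = 0.218), so the camera calls depend on the preset value. That setting also found a list shifted by 0.3 in 0 of 20 simulations, so it cannot show that a list was unmoved. Fry called 12 lists, all in the direction that camera gave, and 0 with the slide as a block. The shifts below are medians over a list's members; the median over all tested genes was -0.05.

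Cell cycle genes rose together. Of 29 measured, 27 had positive values, 0 passed over all genes, and 13 passed when adjusted over the list alone. The median was 0.60 (0.63 on slide 1 and 0.55 on slide 2; camera adjusted p = 9.02e-21; adjusted p = 0.218 with an estimated correlation). Examples were Mcm6, part of the replicative helicase (0.99 ± 0.15), the mitotic kinase Cdk1 (0.94, 0.25 from a second probe) and Birc5 (0.81, with 0.10 and 1.41 as the lowest and highest of its probes). Cdc6 was well above background on 1 of the 2 control arrays and gave 2.72 and 0.49 on the slides.

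Immunoglobulin and plasma cell genes also rose (median 0.59, 0.77 and 0.44 on the slides, and 0.20 with normexp; adjusted p = 1.72e-10; adjusted p = 0.218 with an estimated correlation). Of 20 measured members 15 were positive, 0 passed over all genes, and 9 passed adjusted over the list alone, among them Ighg1, Igkc, Jchain and Iglv1 (1.51, with 4.41 from a second probe). The members that define plasma cells apart from their antibodies did not all move this way. Derl3, a secretory pathway gene, differed by 1.19, whereas Sdc1 was at -0.42 and Prdm1 and Irf4 were at 0.08 and -0.33. B cell markers had a median of -0.18 and did not pass (adjusted p = 0.212), with Fcmr at -0.79 and H2-Ob at -1.44, for which a second probe gave 1.12.

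Podocyte markers rose, with a median of 0.28 (0.23 and 0.30 on the slides; adjusted p = 6.84e-09; adjusted p = 0.218 with an estimated correlation). Of 24 measured, 18 were positive and 4 passed adjusted over the list alone (Cdkn1c, Cd55 and Tcf21 among them) and 0 over all genes. Cdkn1c, a cell cycle inhibitor made by mature podocytes, differed by 2.03 ± 0.16, Cd55, a membrane regulator of complement, by 1.01, and Ptpro by 0.87. Fibroblast, mesangial and smooth muscle markers rose by a median of 0.30 (0.13 with normexp; adjusted p = 1.45e-05), with Lum at 0.66 and Dcn at 0.57, 0 of 17 members passing over all genes or over the list alone. Endothelial markers were higher by the test (adjusted p = 0.0171) with a median of 0.02, with Plat at 0.58, Ehd3 at 0.51 and Erg at -0.47. Of 19 measured endothelial markers 11 were positive and 8 negative, and 0 passed over the list alone. With an estimated correlation the adjusted p was 0.218 for the fibroblast, mesangial and smooth muscle list and 0.248 for the endothelial list. Proximal tubule markers (median -0.09, 0.01 with quantile normalization, 28 measured) and loop, distal tubule and collecting duct markers (median -0.03, 23 measured) did not pass, with adjusted p of 0.907 and 0.971.

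Matrix, injury and inflammatory genes were higher as lists, while no single member passed over all genes. Extracellular matrix and fibrosis genes had a median of 0.17 (adjusted p = 1.45e-05), and 0 of 34 passed over the list alone. Loxl2, a collagen crosslinker, was at 1.02 ± 0.16 and Sparc at 0.73, with 0.44 and 0.21 as the lowest of their probes. Tubular injury markers had a median of 0.21 (adjusted p = 3.26e-06), and 3 of 27 passed adjusted over the list alone, with Fgb at 1.44 (0.57 with normexp), the intermediate filament gene Vim at 1.29 ± 0.14 and Anxa3 at 0.81. Chemokines and inflammatory cytokines had a median of 0.20 (0.13 with normexp; adjusted p = 2.33e-05) and 4 of 27 passed adjusted over the list alone, with Ccl8 at 1.63, Ccl28 at 1.34, Cxcl1 at 1.12 and Cxcl13, which attracts B cells, at 1.01. With normexp Ccl8 was at 1.08, Cxcl1 at 0.41 and Cxcl13 at 0.35. Neutrophil markers were at a median of 0.39 (0.22 and 0.52 on the slides; adjusted p = 1.32e-05), with S100a8 at 1.49 and S100a9 at 0.93, 3 of 12 passing over the list alone. Macrophage and dendritic cell markers (median 0.10; adjusted p = 0.00173) included Ms4a7 at 0.84 and Itgam at 1.13, for which another probe gave -0.21. With an estimated correlation the adjusted p of these 5 lists ran from 0.218 to 0.237. T and NK cell markers were lower (median -0.17; adjusted p = 0.0441; adjusted p = 0.52 with an estimated correlation), and the call ended with the slide as a block (adjusted p = 0.0598). Interferon response genes did not pass (median -0.11; adjusted p = 0.132).

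Complement genes were higher (median 0.19; adjusted p = 4.63e-05; adjusted p = 0.23 with an estimated correlation). Of 25 measured members 19 were positive and 1, Cfd, passed over all genes and over the list alone. Cd55 was at 1.01, Masp2, a protease of the lectin pathway, at 0.86, with 0.24 as the lowest of its probes. Antigen processing and presentation genes (median 0.14; adjusted p = 0.0171), unfolded protein response genes (median 0.27; adjusted p = 2.33e-06) and erythroid genes (median 0.29; adjusted p = 0.00043) were higher too, with adjusted p from 0.218 to 0.237 under an estimated correlation. The unfolded protein response list held Chac1 at 0.68, Creld2 at 0.66 and the chaperone Hspa5 at 0.52. The erythroid list, which marks blood in the samples, held Ahsp at 1.38 (0.74 with normexp) and Alas2 at 0.78, while Hemgn was at -0.96.

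Lipid metabolism lists were lower. Cholesterol synthesis genes fell by a median of 0.23 (-0.26 and -0.25 on the slides; adjusted p = 6.91e-05), with 20 of 24 members negative and 0 passing over the list alone. Insig1, which restrains sterol synthesis, was at -0.48 ± 0.14 and the isoprenoid enzyme gene Idi1 at -0.47. Fatty acid oxidation and PPAR target genes had a median of -0.17 (-0.19 and -0.22 on the slides; adjusted p = 0.00144), with 24 of 28 negative and 1, Pdk4, passing adjusted over the list alone. Angptl4, an inhibitor of lipoprotein lipase, was at -0.84. With an estimated correlation the adjusted p of these 2 lists was 0.23 and 0.218. The lists of oxidative phosphorylation (median -0.10) and oxidative stress and NRF2 targets (-0.04) did not pass, and both medians were above 0 with quantile normalization (0.01 and 0.03). Likewise metallothionein genes (-0.08, Mt2 at -0.61), WNT pathway genes (-0.09), tight junction and claudin genes (-0.01, and 0.00098 with scaling to the median of detected probes), apoptosis genes (-0.04) and immediate early genes (-0.19) did not pass. The immediate early list held members in both directions, with Ccn1 at -0.90 and Dusp1 at 0.67. In the loop and distal tubule list and the NRF2 list the camera direction was opposite in sign to the median.

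Lists that mark time of day or other tissues also differed. Circadian clock genes were higher as a list (median 0.26; adjusted p = 0.000131; adjusted p = 0.218 with an estimated correlation), and 3 of 20 passed adjusted over the list alone (Per2, Ciart and Arntl). Per2 was at 1.15 ± 0.16 and Arntl, of the activating arm, at -1.14 ± 0.15. Cry1 and Npas2 were each well above background on 3 of the 4 arrays and went from 1.44 and -1.38 to 0.28 and -0.51 with normexp. Adipose markers passed as higher (adjusted p = 0.00303) through 4 of 14 members, Adipoq, Retn, Cidec and Thrsp; the mean was 0.96 and the median was -0.09. Retn was at least 23.2-fold higher, being not well above background on either control array. That bound holds for the main processing, and with normexp the log2 difference of Retn was 2.43. The list of skeletal muscle, pancreas and liver markers was higher by the test (adjusted p = 0.00766; median 0.08, and -0.01 with normexp background correction), with 4 of 14 members passing over the list alone, the liver-made plasma proteins Ahsg (3.11, 1.56 with normexp, well above background on 1 control array), Fgb (1.44), Ttr (1.40) and Alb (1.02). Adrenal markers were lower (median -0.36, or -0.22 with members near background at their bound, 9 measured; adjusted p = 0.00687), with Akr1b7 at -0.58 and Hsd3b1 not well above background on either MN array. With an estimated correlation the adjusted p of these 3 tissue lists was 0.23.

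**Figure D3:**
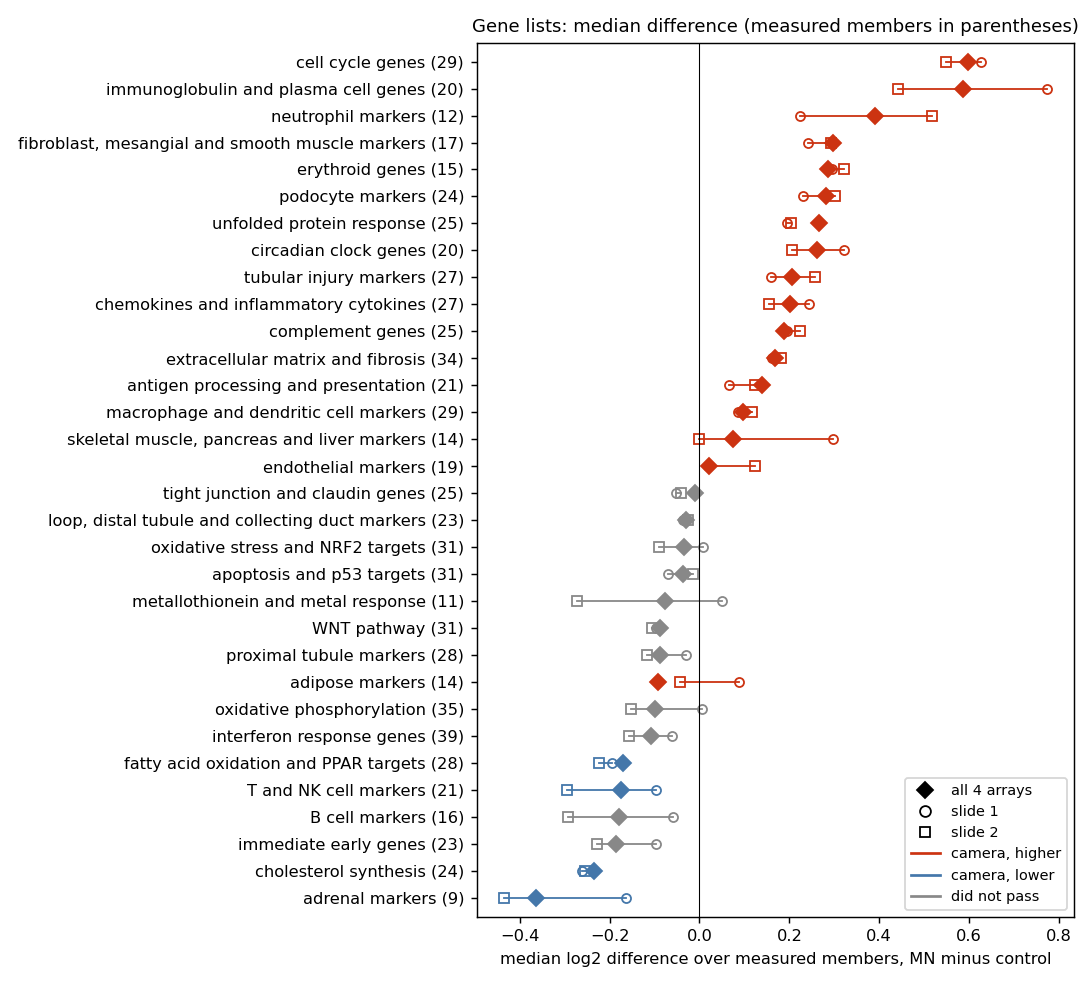
Median log2 difference, MN minus control, over the measured members of each of 32 gene lists (number measured in parentheses): diamonds for all 4 arrays, circles for slide 1 and squares for slide 2. Red and blue mark lists that camera called higher and lower at its preset correlation, grey those it did not call; cell cycle genes stand at 0.60 and adrenal markers at -0.36.

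The third comparison described how the 4 arrays varied. Arrays of 1 slide were closer to each other than arrays of 1 group. Across genes, which are not independent replicates, the Pearson correlation was 0.990 and 0.989 for the control and MN array of slides 1 and 2, 0.985 between the 2 control arrays and 0.987 between the 2 MN arrays. The SD of log2 differences was 0.437 and 0.468 within slides and 0.541 and 0.520 within groups. The first principal component held 54.3% of the variance and separated the slides, and the second held 33.7% and separated control from MN. The differences of MN from control on the 2 slides correlated at 0.49 across genes.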

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

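The main count was 5 genes, all differing by 2-fold or more. It was 16 with quantile normalization, 9 with scaling to the median of detected probes, 16 with eBayes trend and 22 at adjusted p under 0.1, 0 with no filter (34593 genes tested) and 0 with probes well above background on all 4 arrays, a filter that leaves out Adipoq, Mup18 and Cfd; the count of genes at 2-fold or more was equal to it in each case. Where neither more nor fewer genes were tested, the cause was not tested. It was 7 with normexp, of which 3 were among the 5 (without Adipoq and Mup18), and 7 with the deposited value table, every probe on its own (probes) or the mean of probes, and 5 with eBayes robust. With the slide, and so the replicate number, as a block it was 0 for both counts. Without any 1 array it was 0 for both counts (range 0 to 0), the lone array being assumed to vary like the other group. At an unadjusted p under 0.05 limma then gave 431 genes higher and 1772 lower without control replicate 1, 852 and 601 without control replicate 2, 638 and 893 without MN replicate 1, and 541 and 454 without MN replicate 2. At an unadjusted p under 0.05 the higher share was 50.3% in the main setting, 60.7% with quantile normalization (1005 higher and 652 lower) and 41.0% with the block; without control replicate 1 the median of all genes was -0.15.

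The number of lists called was 21 (17 higher, 4 lower). It was 0 with an estimated correlation and 12 with fry (11 higher, 1 lower), and 20 with the block (0 with fry and the block, smallest adjusted p 0.105, and 0 with an estimated correlation and the block); without 1 array it ran from 15 to 19. Of the 21 lists, 10 kept their call in all 15 settings run with camera at its preset correlation or on ranks: cell cycle, immunoglobulin and plasma cell, podocyte, fibroblast, neutrophil, tubular injury, chemokine, complement, unfolded protein response and circadian genes. The 15 include eBayes trend and eBayes robust, which do not enter camera and so could not alter a call. T and NK cell markers lost it in 7. The excess of the SD of log2 differences within groups over that within slides was 0.078, 0.123 with normexp and 0.128 among probes well above background on all 4 arrays, and 0.017 to 0.077 without 1 array.

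Some values changed sign, and the cause was not tested. None of the genes below was past the threshold in either case. With quantile normalization Nphs1 was at 0.085, Ighg2c at 0.041, proximal tubule markers at 0.0086, oxidative phosphorylation at 0.011 and oxidative stress and NRF2 targets at 0.029. The skeletal muscle, pancreas and liver markers were at -0.013 with normexp and tight junction and claudin genes at 0.00098 with the median of detected probes. With every probe on its own H2-Ob was at 1.12 and Mt1 at 0.45, and with the mean of probes Mt1 was at 0.11 and the NRF2 list at 0.0012. Without 1 array the values ran from -0.22 to 0.78 for H2-Aa, -0.11 to 1.05 for Nkd2, -0.70 to 0.10 for Pck1, -0.86 to 0.38 for Cox6c, -1.12 to 0.68 for Atp5o, -0.51 to 0.14 for Sdhb, -0.25 to 0.21 for Nphs1, -0.92 to 0.025 for Iigp1, -1.07 to 0.016 for Gzmb, -1.07 to 0.32 for Cyp11b1 and -0.31 to 0.028 for Ighg2c. For list medians they ran from -0.078 to 0.0082 for tight junctions, -0.11 to 0.21 for muscle, pancreas and liver, -0.21 to 0.10 for proximal tubule, -0.0010 to 0.14 for endothelial markers, -0.29 to 0.15 for oxidative phosphorylation, -0.15 to 0.060 for NRF2 and -0.049 to 0.10 for adipose markers. The median signal was 3.18 to 5.37 times the local background, which limits the fold changes of dim genes.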

Other observations

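Antibody gene segments beyond the fixed list were examined after their values were seen. Of 80 measured segments and constant regions 65 had positive values, 37 were at 2-fold or more, and in 52 both MN arrays lay above both control arrays (7 below). The median log2 difference was 0.84 (1.07 on slide 1 and 0.74 on slide 2). It was 1.02 over 49 kappa variable segments, 0.59 over 22 heavy variable segments and 0.97 over 8 constant regions, and 1 segment, Igkv3-10, passed over all genes. Related segments share sequence, so the segments are not independent of each other. A segment could enter through the MN arrays alone. Igkv3-12, Igkv8-18 and Igkv5-39 were not well above background on either control array, so the sizes of their differences are uncertain. With normexp the median of the fixed immunoglobulin and plasma cell list went from 0.59 to 0.20. Across the genes, 33.1% had MN arrays that both lay beyond both control arrays on 1 side, where chance gives 33.3% for exchangeable arrays. Arrays of 1 slide resembled each other, so the arrays were not exchangeable. The shares therefore do not show whether MN differed more than by chance.

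Of the tests below, those on fat and liver tissue were written before the values of their gene lists were seen, and those on the clock genes and on the slides were chosen after the result was seen. The rule that a tissue is argued against only where the upper quartile of its list is low too was added after the values were seen.

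Transcripts typical of fat (Adipoq and Cfd) and of liver (Mup18) were higher in MN, and Retn and Ahsg passed when adjusted over their lists alone (adjusted p = 0.296 and 0.160 over all genes). If fat tissue came along with the MN kidneys, other transcripts abundant in fat should be higher by similar amounts. In a second fat list the 7 members at a low level in control had a median log2 difference of 0.37 (quartiles 0.04 and 0.47). Mrap was at 1.11, Adig at 0.53, Plin1 at 0.40 and Lipe at -0.26. This argues against similar rises across fat transcripts. A small amount of fat stays open, since it would raise these members less than Adipoq. Their control levels were higher (-3.98 for Plin1 and -1.06 for Aoc3, against -7.26). In the first fat list 6 of 14 members were positive and 8 negative, with Cidec at 2.59 and Thrsp at 0.78. For liver the median of 15 such members was 0.47 (quartiles 0.06 and 0.83), with Rbp4 at 2.03 and Cps1 at -0.46; it also lay under the bound of 0.5 set beforehand, but by less than the spread of the members, so liver tissue as the source stays open. A response of kidney cells to the disease was not tested and stays open too.

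In the clock list Per2, Ciart and Arntl passed adjusted over the list alone, at 1.15, 1.09 and -1.14 (adjusted p = 0.346, 0.408 and 0.320 over all genes). A different time of day at sampling, which the labels do not give, should move other genes driven by E-boxes: 8 such genes without Per2 and Ciart had a median of 0.147 (quartiles 0.0014 and 0.23, 6 positive), with Nr1d2 at 0.57 and Nr1d1 at -0.59, which leaves it open. Each slide and scan held 1 control and 1 MN array, so a difference shared by the arrays of a slide cancels within it. The fixed list of 20 clock genes had medians of 0.32 and 0.21 within the slides. This argues against a difference between slides or scans as the whole source. With the slide as a block, camera at its preset correlation kept the call of the list (adjusted p = 0.000195). An estimated correlation (adjusted p = 0.453) and fry (adjusted p = 0.105) did not call it. A stronger glucocorticoid signal stays open: 11 of 16 response genes were positive with a median of 0.116, Fkbp5 and Zbtb16 were at 1.48 and 2.33, and Pdk4 was at -1.62. That median met the bound written against this signal. The upper quartile, 0.67, was used in place of the median, and the members spread widely (lower quartile -0.22). An effect of the disease on the clock was not tested.

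Arrays of 1 slide lay closer together than arrays of 1 group, by 0.078 in the SD of log2 differences, and a split of the arrays by slide gave 5121 genes at an unadjusted p under 0.05 against 1776 for MN against control (0 and 5 by limma's adjusted p) and 133 for the remaining split. This may reflect a difference between slides or scans, or between the replicates, which cannot be separated from the slides. Group labels exchanged on 1 slide are argued against, since 89.8% of genes at 2-fold or more within both slides had the same direction (318 against 36). Probes near background are argued against as the source, since the excess was 0.128 among genes well above background on all 4 arrays. With 3 splits of 4 arrays no share under 0.05 can be reached.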
